A study of Glycine max with 6 samples.

How the data were processed

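Total RNA from soybean cotyledons of 150 mg was labelled with a one-cycle kit, per the labels, and hybridised to an Affymetrix array. Files held 6 arrays, 2 technical replicates for each of 3 samples: a nontransgenic control and 2 independent RNAi lines. Values were the authors' deposited probe set signals, an intensity on a linear scale. They were already on a common scale, as found from the values: after leaving out the lowest and the highest 2% of probe sets, the mean of each array was 500.1. The software, its version and any scan settings are not given in the sources used here. No genome build is named, so no coordinates are given.

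Array medians over all 61170 probe sets ran from 57.8 to 72.4. Of these probe sets 37593 were for soybean and 23350 for the other organisms on the array (15820 and 7530 in the 2 sets), with 135 Affymetrix controls, 48 soybean rRNA controls and 44 Phytophthora rRNA controls. Gene names came from the platform annotation, with symbols updated through gene identifiers in the RefSeq gene table of assembly Glycine_max_v4.0, where 8652 of 9047 listed probe sets were found. Of the soybean probe sets 8681 had 1 gene symbol, 366 several and 28546 none, and no gene was named from a probe set with several. Of the tested probe sets, 1193 had 1 symbol other than a numbered placeholder, and these alone count as named among the largest changes. The annotation lists GY4 under more than 1 gene record with the same symbol.

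Signals of other organisms' probe sets served as background. A soybean probe set was detected if it lay above the 95th percentile of those on both arrays of at least 1 sample (68.4 to 91.7 by array), which left 27460 to test and 10133 out. The test scale was log2(signal + 16), which understates changes of dim probe sets. A named probe set below background on every array of the control, or of both lines, has only a bound there. Its difference is given as at least N-fold, from the mean log2 signal of the brighter side against that of the dimmer side with each array at its background bound or the signal, whichever was higher, and as no fold where this came below 1. Its adjusted p is that of the fit. Tests, list medians and ranks use log2(signal + 16) throughout. No other scaling was done.

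All models used limma 3.58.1 in R 4.3.3, with lmFit and eBayes, and Benjamini-Hochberg adjustment over tested probe sets. For the RNAi lines against the control, the 2 arrays of each sample were averaged first, because the sample is the replicate, which left 3 means and 1 residual degree of freedom (prior 2.36). The control is assumed to vary as the lines do. Single lines were compared on 6 arrays in 3 groups with a shared spread (3 residual degrees of freedom, prior 2.35), so that these p-values measure technical spread. Lists were tested with camera on the 3 means with a preset correlation of 0.01, with at least 5 tested probe sets, adjusted over 17 lists, and again with an estimated correlation. The latter test rests on the 1 residual degree of freedom, so it could hardly call a list. It was also run on the 6 arrays, with 3 residual degrees of freedom.

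The design, the rule for named genes, the themes of the 21 gene lists and the alternatives were chosen before the data were examined. The lists had been written as words in gene descriptions, and the tables used here hold only symbols, so their members were assigned from symbols afterwards, before any comparison was computed. For 3 lists (oil body proteins, amino acid and peptide transport, RNA silencing) no symbol could be assigned. Named are every gene of the glycinin and beta-conglycinin lists, at the probe set of highest mean, with others given beside it. Also named are the 10 largest rises and the 10 largest falls called in the RNAi lines against the control and changed the same way on every RNAi array against every control array, and in each list 2 to 4 members of largest absolute change among probe sets with 1 gene, called or not. The rule also names the 5 largest differences each way between the lines among those called, of which there were none, and at most 2 unnamed probe sets each way.

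Alternatives were quantile normalization, median centring, no filter, a filter at the 99th percentile of background, pseudocounts of 1 and 64, eBayes with an intensity trend or robust, each array left out, the replicate number as a block, arrays as replicates, duplicateCorrelation with the sample as a random block, camera with an estimated correlation, fry, and 1 probe set per gene. Scaling each array to the geometric mean of its poly-A spike probe sets, and camera with an estimated correlation and no filter, were added after seeing the data. When an array was left out, the set of tested probe sets was kept.

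The fits were tested on simulated data with the real probe sets, their mean signals and technical spread, and 200 of 27460 changed. For the RNAi lines against the control 97.1% of 4-fold and 21.6% of 2-fold changes were recovered, with 8 false calls among 129. For line 1 against the control these were 93.2% and 54.6%, with 6 false calls among 155, and for line 2 against the control 93.2% and 53.6%, with 9 among 157. With 7000 changed, 99.9% of 4-fold and 98.0% of 2-fold changes were recovered for the RNAi lines against the control, with 345 false calls among 7275. No variation between samples was simulated, so a deviation of the single control sample is left out and these rates are best cases. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.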

Results

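Transcript levels were measured in cotyledons, the storage organs of the soybean (Glycine max) seed, taken at a weight of 150 mg. There were 3 samples: a nontransgenic control and 2 independent transgenic lines made to suppress seed storage proteins by RNA interference (RNAi), in which double-stranded RNA directs the breakdown of matching transcripts. Each sample was hybridised to 2 technical replicate arrays, 6 in all, of a short-oligonucleotide array with 37593 soybean probe sets, each a group of probes, 366 of them with more than 1 gene symbol. The labels did not state which storage protein genes the construct targets or how many seeds made up a sample. Signals were on a linear scale, and the number of arrays limits their precision. The median signal over all probe sets ran from 57.8 to 72.4, and soybean probe sets above background numbered 26459 to 27396 per array. Changes are given as log2 differences, and 27460 detected soybean probe sets were tested. They are relative to the deposited scaling of whole arrays, by which the median tested probe set moved by 0.02; scaled to the spiked-in poly-A control RNAs instead, an alternative chosen after seeing the data, it moved by 1.48. The control is 1 sample, so its handling and its genotype cannot be told apart.

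The first comparison set the mean of both RNAi lines against the control and asked which transcripts differ when storage proteins are suppressed. The storage protein transcripts themselves came first. GY3 and GY2, which encode subunits of glycinin, the legumin-type globulin of the soybean seed, and CG-BETA-1, which encodes the beta subunit of beta-conglycinin, the vicilin-type globulin, fell in both lines. GY3 went from control signals of 17950 and 20900 to signals between 1640 and 1892 on the 4 RNAi arrays, a 10.9-fold drop (log2 change -3.44, SE 0.10, adjusted p = 0.0488). CG-BETA-1 went from 54090 and 55580 to between 12910 and 13410, a measured 4.14-fold drop (log2 change -2.05, SE 0.10), and its other probe set gave -2.18. The sizes of these changes are not ranked, since CG-BETA-1 starts from control signals of at least 30000, where changes spread less, and GY3 from lower ones.

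GY2 fell by 1.42 on the log2 scale at its brightest probe set, with a signal of 50805 in the control and 18920 ± 450 (SD, n = 2 lines) in the RNAi lines, and its other probe set gave -2.73. GY1 had log2 differences of -0.99 and -0.84 at its probe sets, with the signal lower on every RNAi array than on both control arrays, but its adjusted p-values of 0.0538 and 0.0632 missed the threshold. GY5 stood at 54284 in the control and 45900 ± 4830 in the lines, a log2 difference of -0.26 (adjusted p = 0.276). GY4 had differences of -0.21 and -0.19 at its probe sets, neither called, and both turned to 0.048 and 0.035 after quantile normalization. GY7, a glycinin gene of low signal, had a difference of the opposite sign, with 288 in the control and 607 ± 32.1 in the lines (log2 difference 1.04, adjusted p = 0.0526).

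A probe set shared by several beta-conglycinin genes had a log2 difference of -0.93 (adjusted p = 0.0581), and the CG-1 probe set, dim at 143 in the control, one of -0.84 (adjusted p = 0.203). In all, 3 of the 9 glycinin probe sets and 2 of the 4 beta-conglycinin probe sets were called, and 6 and 3 with p-values adjusted over the list alone. Of the storage protein probe sets 10 had a control signal of at least 30000, with the highest, 64725, at the shared beta-conglycinin probe set. These 10 had differences from -2.73 to -0.19, and 4 of them, of GY2 and CG-BETA-1, were called. Over 195 probe sets of other genes with a control signal of at least 30000, the median log2 change was -0.19 and its median absolute deviation 0.11, against -0.04 and 0.34 at control signals of 1000 to 3000 (2 of the 195 were called). The differences of GY4 and GY5 lie within 1 median absolute deviation of that median of -0.19, inside the spread of other genes of such signal.

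**Figure D1:**
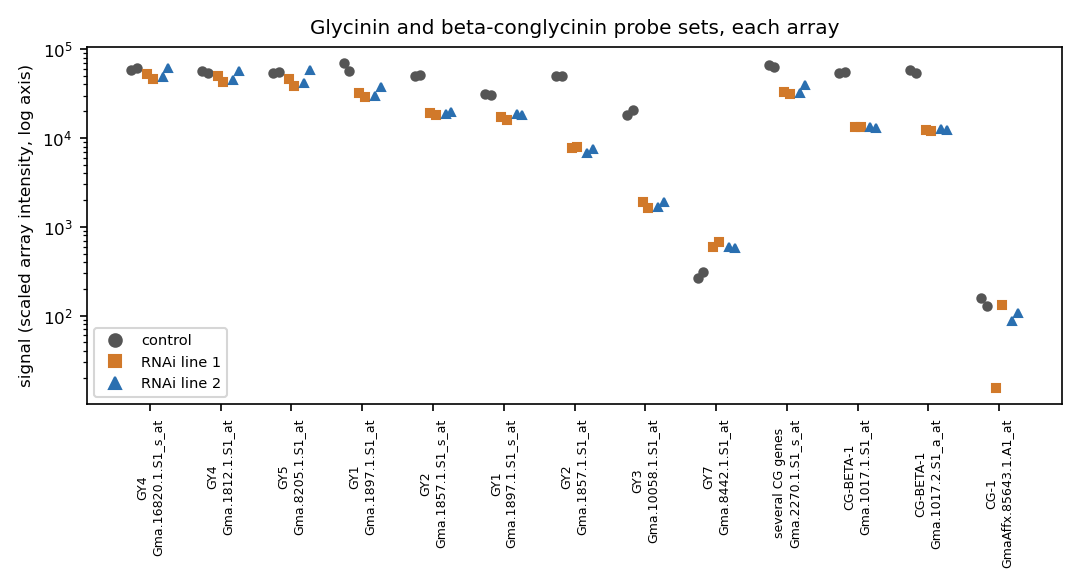
Signal of each glycinin and beta-conglycinin probe set on each of the 6 arrays (vertical axis, scaled array intensity on a log axis; horizontal axis, probe sets ordered by mean signal within each family; 1 point per array). GY2, GY3 and CG-BETA-1 sit lower on all 4 RNAi arrays, with GY3 near 1773 against 19426 in the control. At GY4 and GY5 only replicate 2 of line 2 reaches the control signals, and the other RNAi arrays lie below both control arrays.

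Beyond the storage proteins, the 10 largest named rises included a sugar transporter, pigment, stress and seed maturation genes. SWEET24, of a family of sugar transporters, rose 7.15-fold (log2 change 2.84, SE 0.10, adjusted p = 0.0488), from a signal of 395 in the control to 2967 and 2870 in the lines. DFR1, dihydroflavonol reductase of the anthocyanin pathway, rose at least 1.8-fold (adjusted p = 0.0488), given as a bound because its signal was below background on both control arrays. Its place among the largest rises depends on the pseudocount of 16. VSPA, a vegetative storage protein otherwise abundant in leaves, rose by 2.37, with 2.04 at another probe set, although its remaining probe sets gave 0.98 and -0.02 and were not called. BG7S-2, a basic globulin of the seed, rose by 2.23 to signals of 6333 and 6858, and SCB1, a protein first known from the seed coat, rose by 2.103. The small heat shock protein gene HSP23.9 rose by 2.21, and by 1.99 and 1.72 at its other probe sets. HSP90A1 rose by 1.98 at the probe set chosen, where 1 control array was below background, with 0.65 at another that was not called and a further probe set below background in the control and line 2. GASA4, of a family of small gibberellin-regulated proteins, rose by 2.08, the seed maturation gene PM22 by 1.77 and SBP65, a biotin-containing seed protein, by 1.71.

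The 10 largest named falls held GY3, GY2 and CG-BETA-1 together with ferritin, fatty acid desaturase and cell wall genes. SFERH-2, which encodes a ferritin, the iron-storing protein of plastids, fell by 2.48 on the log2 scale (SE 0.14), with changes from -2.47 to -1.36 at its other probe sets, all called. A further ferritin gene, H-1, fell by 1.63 (SE 0.10), with -1.21 at a probe set that missed the threshold (adjusted p = 0.0531). FAD2-2, an oleate desaturase, fell 4.11-fold, from a signal of 12610 to 3097 and 2983 (log2 change -2.04, SE 0.10), with -1.199 at another probe set that was also called. The transcription factor gene MYB138 had changes of -1.55 and -1.43 at its probe sets, both called. BBI-2, a Bowman-Birk type protease inhibitor, fell by 1.53, and the proline-rich cell wall protein genes PRP2 and SBPRP had changes of -1.51 and -1.43, both called, with -1.16 at another probe set of PRP2 that was not (adjusted p = 0.0561). On the scale of the test, the largest rise of a probe set with no gene name in the tables used here was 4.41, from a signal of 94.3 in the control to 2281 and 2333 in the lines. The largest such fall was from 926 to below background on all 4 RNAi arrays, at least 11.6-fold (adjusted p = 0.0488), and its rank depends on the pseudocount.

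Over all tested probe sets, limma called 451 at an adjusted p below 0.05, 288 higher and 163 lower in the RNAi lines, all at least 2-fold apart on the log2(signal + 16) scale, and 448 of them lay beyond both control arrays on all 4 RNAi arrays. At an unadjusted p below 0.05 there were 9095. Of the calls, 66 of the higher were below background on both control arrays and 21 of the lower on all 4 RNAi arrays, so that the size of these changes is only a bound, under 2-fold for DFR1. With arrays scaled to the poly-A spikes 26353 were called higher and 67 lower. The adjusted p-values of the 451 calls with the deposited scaling all lay between 0.0488 and 0.0498, on 1 residual degree of freedom. The count was 0 after quantile normalization, median centring, no filter, a pseudocount of 1 or robust moderation. It was 3323 with the stricter filter, 3547 with a pseudocount of 64 and 8517 with an intensity trend. Leaving out any 1 of the 4 RNAi arrays left 0 calls, and leaving out control replicate 1 or 2 gave 1231 or 1884.

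Gene lists with themes chosen for seed tissue describe these changes by group. Of 21 lists, 17 had at least 5 tested probe sets, and 3 differed from the other genes by camera with a preset correlation between genes of 0.01. Glycinin was lower (median -0.84, 8 of 9 probe sets lower, or 6 of 9 after quantile normalization, where GY4 turned upward, and 2 of 9 with arrays scaled to the spikes, with GY4 and GY5 inside the spread of other genes of such signal; adjusted p = 0.00196), LEA and dehydrins were higher (median 0.41, 26 of 39 higher, or 33 of 39 after quantile normalization and 39 of 39 with arrays scaled to the spikes, adjusted p = 0.000266), and fatty acid and oil synthesis was lower (median -0.29, 27 of 33 lower, or 2 of 33 with arrays scaled to the spikes, adjusted p = 0.000266). With an estimated correlation the adjusted p was 0.719 for each of these lists, so no list was called. That test rests on 1 residual degree of freedom, on which a list could hardly pass. Run on the 6 single arrays, with 3 residual degrees of freedom, it called no list either. The adjusted p there was 0.602 for glycinin, 0.437 for LEA and dehydrins and 0.437 for fatty acid and oil synthesis. On the 3 means the estimated correlation was 0.222 for glycinin and 0.129 for fatty acid and oil synthesis, both above the preset value. For LEA and dehydrins it was -0.02, below the preset value, and the call was lost all the same. On the 6 arrays it was above the preset value in each: 0.409 for glycinin, 0.028 for fatty acid and oil synthesis and 0.057 for LEA and dehydrins. With so few degrees of freedom, these losses do not decide whether correlation between genes accounts for the calls. The glycinin call was also lost after quantile normalization (adjusted p = 0.0688) and with 1 probe set per gene (adjusted p = 0.0656). With arrays scaled to the spikes 99.3% of all tested probe sets stood higher, so the counts of higher and lower members there follow that offset. Camera, which compares a list with other genes, called the same 3 lists there, each in the same direction. Such scaling moves nearly all changes by about the same offset, so these directions could hardly turn and the calls add no further support.

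LEA proteins and dehydrins accumulate late in seed development and protect cells during drying. In this list 7 of 39 probe sets were called higher and 0 lower, and 20 passed with p-values adjusted over the list alone. PM22 (1.77), PM29 (1.67), PGMPM18 (1.55) and PM35 (1.48) had the largest changes among probe sets with 1 gene, and all rose. A probe set shared by a dehydrin gene and another of the list had 2.03, also called. In fatty acid and oil synthesis, 4 of 33 probe sets were called lower and 0 higher, with 18 adjusted over the list alone. FAD2-2 (-2.04) and FAD2-3 (-1.29), both oleate desaturase genes, fell, while FAD2-1A, with control signals of 40963 and 47652 at its probe sets, had -1.31 and -1.16 (adjusted p = 0.0514 and 0.0505). DGAT1A, which encodes an enzyme of the last step of oil assembly, had 1.19 in the other direction (adjusted p = 0.0507). Counts adjusted over the list alone do not mark these 2 lists out. They were 27 of 56 in flavonoid synthesis, 9 of 15 in seed coat and cell wall markers and 17 of 65 in seed regulators, lists that camera did not call. Over all tested probe sets, 33.1% had an unadjusted p below 0.05.

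**Figure D2:**
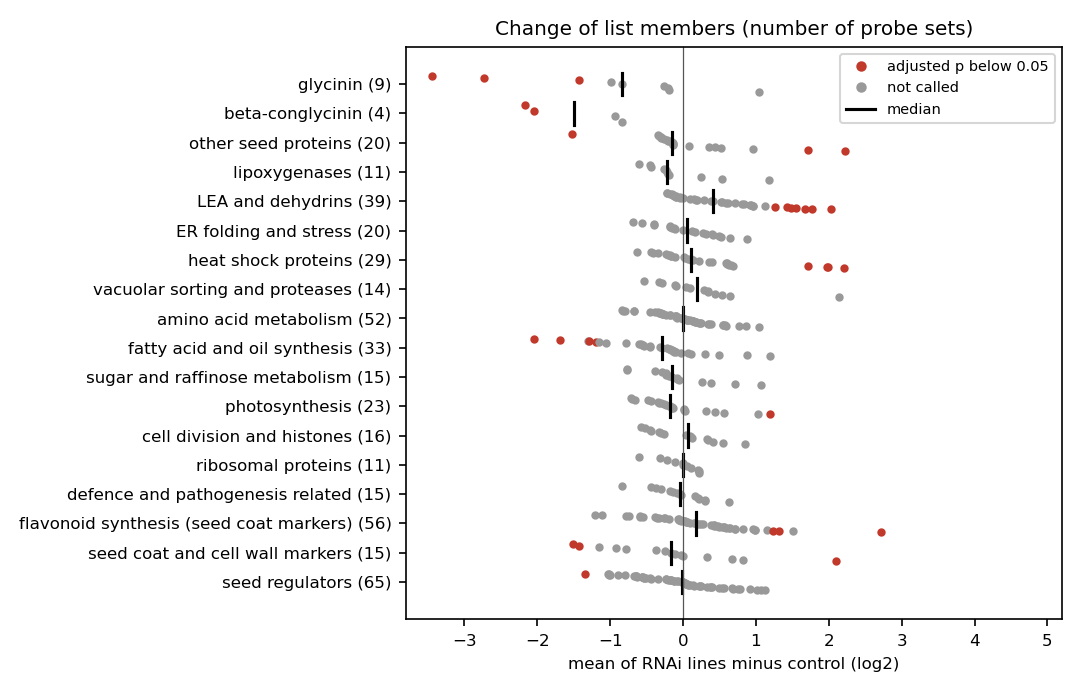
Log2 difference between the mean of the RNAi lines and the control (horizontal axis) for each tested probe set of each list (rows, number of probe sets in brackets). Red points passed an adjusted p below 0.05, grey points did not, and black bars are medians; the medians were -0.84 for glycinin, 0.41 for LEA and dehydrins and -0.29 for fatty acid and oil synthesis.

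The other tested lists did not differ from the rest of the genes as groups, though some members changed. Among 20 probe sets of other seed proteins, BG7S-2 and SBP65 rose and BBI-2 fell. The median of that list was -0.15 but its mean 0.10, its test pointed down (adjusted p = 0.686), and its median turned to 0.055 after quantile normalization. The 12 probe sets of that list with control signals of at least 30000, trypsin inhibitors and other abundant seed proteins, had log2 differences between -0.34 and 0.09, and 0 of them were called. Among heat shock proteins 4 of 29 probe sets were called higher, those of HSP23.9 and HSP90A1 (list median 0.11, adjusted p = 0.261). In ER folding and stress 0 of 20 were called (list median 0.06, adjusted p = 0.686). BIP4, a chaperone of the endoplasmic reticulum, had 0.88 (adjusted p = 0.0594) and 0.32 (adjusted p = 0.143) at its probe sets. The latter was the brighter in the control and the dimmer in both lines. NRP-A had -0.69 and -0.57. In flavonoid synthesis, taken as markers of the seed coat, 3 of 56 were called, all higher, DFR1, F3H (1.32) and 4CL1 (1.23), the last without separating every RNAi array from both control arrays (list median 0.18, adjusted p = 0.109). At that 4CL1 probe set 1 control array was below background, and neither line compared on its own was called by limma (adjusted p = 0.252 and 0.274). Other probe sets of F3H and 4CL1, with 0.98 and 0.53, were not called. IFR1, below background on both control arrays, was at least 1.51-fold higher (adjusted p = 0.0507), with 0.56 at another probe set. Seed coat and cell wall markers were split, with SCB1 higher and PRP2 and SBPRP lower (list median -0.17, adjusted p = 0.261), and the peroxidase gene LOC547499 had -0.93 and -0.78.

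Among seed regulators, a list of mostly bZIP transcription factors, 1 of 65 probe sets was called, BZIP124, which fell by 1.35, and BZIP77 (1.12 and 0.79), BZIP117 (1.07) and BZIP59 (-1.03 and -0.64, and below background in both lines at another probe set) missed the threshold (list median -0.02, adjusted p = 0.354). In amino acid metabolism 0 of 52 were called, and the largest differences went both ways: at least 1.78-fold higher for LOC547953, a glutamine synthetase gene below background on both control arrays, 0.87 for CGS2, of methionine synthesis, with 0.23 to 0.59 at its other probe sets, -0.83 and -0.68 for the glutamate dehydrogenase gene GDH1 and -0.83 for the asparaginase gene ASP1 (list median -0.003, adjusted p = 0.725). Photosynthesis had 1 of 23 called, the early light-induced gene ELIP, which rose by 1.19. ATPC, of the chloroplast ATP synthase, had 1.02 (adjusted p = 0.0526), NDHK -0.71 at a probe set below background in line 2 but 0.02 at its brighter one, and the light-harvesting gene LOC547819 -0.69 and -0.66 (list median -0.18, adjusted p = 0.261). Vacuolar sorting and proteases had 0 of 14 called, with R1, below background on both control arrays, at least 2.87-fold higher (adjusted p = 0.0531), and 0.65 and 0.44 for the aspartic protease gene SOYAP1 (list median 0.19, adjusted p = 0.354). Sugar and raffinose metabolism had 0 of 15 called, with the galactinol synthase gene GOLS, below background on both control arrays, at least 1.57-fold higher (adjusted p = 0.0547). LOC547684 had -0.77, with -0.20 and -0.39 at its other probe sets, and the starch synthase gene GBSSIa had -0.77, but -0.08 and 0.26 at its brighter probe sets (list median -0.15, adjusted p = 0.354).

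No member was called in lipoxygenases (median -0.22, or 0.22 with no filter, adjusted p = 0.315), where LOX9 was below background in the control and line 1 and VLXC had -0.61, with 1 array of each line below background, or in cell division and histones (median 0.07, with a test that pointed down, adjusted p = 0.76), where EXP4 had 0.85 and the tubulin gene TUBB2 -0.57. The same held for ribosomal proteins (median 0.005 but mean -0.04, median -0.018 after median centring, adjusted p = 0.725), where RPL2 had -0.60 and RPL37 -0.31, with -0.22 and 0.20 at a brighter probe set of each, and for defence and pathogenesis related genes (median -0.04, adjusted p = 0.603), where NDR1b, below background on all 4 RNAi arrays, was at least 1.37-fold lower (adjusted p = 0.0573) and KR1 had 0.63, with 1 control array below background. Beta-conglycinin was too short to test among detected probe sets, with 4 of 4 lower and a median of -1.49, or 2 of 4 lower and a median of -0.04 with arrays scaled to the spikes. With no filter it had 5 probe sets and camera called it lower (median -0.93, adjusted p = 0.0192). With an estimated correlation, run after seeing the data and on 1 residual degree of freedom, the call was lost (adjusted p = 0.74). The lists of oil body proteins, amino acid and peptide transport and RNA silencing had no member among the gene symbols used here.

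Each line was then set against the control on single arrays, to ask whether each independent line on its own carried the change. In line 1 the storage protein genes GY3 (-3.45), GY2 (-1.45 at its brightest probe set) and CG-BETA-1 (-2.04) fell, with adjusted p-values from 0.00227 to 0.00352, and GY1 fell by 1.05 (adjusted p = 0.0196). SWEET24 rose by 2.86, the maturation genes PM22 by 1.75 and PM29 by 1.70, and FAD2-2 fell by 2.01. In all, 3924 probe sets were called in line 1, 2188 higher and 1736 lower, of which 570 and 418 changed at least 2-fold. This test sets the difference against the spread between technical replicate arrays, so it compares these samples and not conditions. The count was 1065 with no filter, 6902 with an intensity trend and 26329 with arrays scaled to the spikes, 26264 of them higher. It was 800 and 1151 without control replicate 1 or 2, 329 and 371 without replicate 1 or 2 of line 1, and 2518 without either array of line 2.

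Line 2 was set against the control in the same way. The storage protein genes GY3 (-3.44, adjusted p = 0.00209), GY2 (-1.40 at its brightest probe set), CG-BETA-1 (-2.06) and GY1 (-0.93, adjusted p = 0.0242) fell. SWEET24 rose by 2.81, PM22 by 1.78 and PM29 by 1.65, and FAD2-2 fell by 2.07. There were 4226 calls, 2329 higher and 1897 lower, of which 595 and 439 changed at least 2-fold, again against technical spread. The count was 1132 with no filter, 7334 with an intensity trend and 26371 with arrays scaled to the spikes, 26300 of them higher. It was 1077 and 1278 without control replicate 1 or 2, 2045 without either array of line 1, and 1103 and 527 without replicate 1 or 2 of line 2.

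To ask how far the independent lines shared their changes, the calls were matched by probe set: 3078 were called the same way in both lines, 1751 higher and 1327 lower, and 2 probe sets were called in opposite directions. The shared calls included GY1, GY2, GY3, CG-BETA-1, SFERH-2, FAD2-2 and FAD2-1A among the lower, and SWEET24, BG7S-2 and DGAT1A among the higher. By list, 20 of 39 LEA and dehydrin probe sets were higher in both and 0 lower, 12 of 33 in fatty acid and oil synthesis were lower and 2 higher, and 5 of 9 glycinin probe sets were lower and 1, GY7, higher. Both comparisons use the same control arrays. In 20 simulated sets of unchanged groups sharing those controls, drawn with the technical spread between arrays alone, 0 probe sets were called the same way, and independent lists of these sizes would share 185.6 higher and 119.9 lower. The changes in the lines had a covariance of 0.217 across probe sets, against 0.0192 in the simulated sets (correlation 0.88 against 0.50; probe sets are not independent replicates), but the simulated sets leave out any deviation of the control sample itself, which both comparisons share. The excess, in overlap or covariance, may come in part or in full from that single control sample. The overlap was 826 with no filter, 5571 with an intensity trend and 25913 with arrays scaled to the spikes, 25862 of them higher. It was 714 and 957 without control replicate 1 or 2, 304 and 340 without replicate 1 or 2 of line 1, and 934 and 496 without replicate 1 or 2 of line 2.

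**Figure D3:**
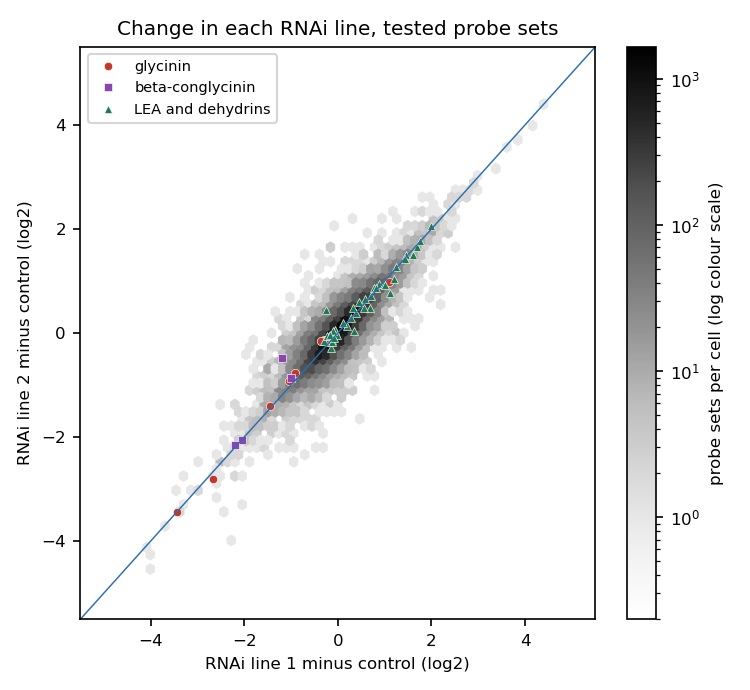
Log2 difference from the control in line 1 (horizontal axis) and line 2 (vertical axis) for the 27460 tested probe sets, drawn as cells shaded by the number of probe sets (log colour scale), with glycinin (circles), beta-conglycinin (squares) and LEA and dehydrin probe sets (triangles) marked. Points lie along the blue line of equal change (correlation 0.88, against 0.50 in unchanged groups simulated with technical spread alone that share the control arrays).

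The last comparison set line 2 against line 1, to ask whether the independent lines differ. No storage protein gene was called between them: GY3 stood at 1766 in line 1 and 1780 in line 2, CG-BETA-1 at 13309 and 13159, and GY4 at 48807 and 55092. SWEET24 (2967 and 2870), PM22 (2774 and 2818) and FAD2-2 (3097 and 2983) were likewise close. limma called 0 probe sets between the lines, with a smallest adjusted p of 0.434, and 1598 of 27460, 5.82%, had an unadjusted p below 0.05. Of the 3 ways to split the 4 RNAi arrays into pairs, the split by line had 57 probe sets with both arrays of 1 pair more than 2-fold above both arrays of the other pair, and the other splits 25 and 21, with 0 calls in each.

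The control probe sets differed between the groups as well. The poly-A spike RNAs, bacterial transcripts added to the sample RNA before labelling, had geometric mean signals of 5871 and 6191 on the control arrays and 2019 to 2139 on the RNAi arrays. The hybridisation controls, added after labelling, stood at 4316 and 4592 against 2914 to 3615. The ratio of the actin 3' to 5' probe sets, a measure of RNA integrity, was 1.197 and 1.211 on the control arrays and 0.845 to 0.943 on the RNAi arrays. That of actin 3' to middle was 0.740 and 0.742 against 0.610 to 0.710. The GAPDH 3' to middle ratio overlapped, with 1.133 and 1.178 against 1.035 to 1.156. The spikes, the hybridisation controls and the actin ratios part the control arrays from the RNAi arrays. This is also the comparison behind the LEA, fatty acid and glycinin values above. Relative to the poly-A spikes, the soybean signals stood higher in the lines by 1.53 and 1.54, an offset larger than many of the falls. With arrays scaled to the spikes, 54 of the 163 lower calls turned to a higher signal in the lines and 109 stayed lower. GY1 (0.55 and 0.70), the brightest GY2 probe set (0.11), FAD2-1A (0.22), FAD2-3 (0.24), PRP2 (0.02) and SBPRP (0.10) turned upward, as did the medians of glycinin (0.70) and of fatty acid and oil synthesis (1.22). Both medians stayed below that of all tested probe sets, 1.48, and camera called both lists lower than other genes, a direction that a shared offset could hardly turn. GY3, CG-BETA-1, SFERH-2 and FAD2-2 stayed lower at the probe sets named first.

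**Figure D4:**
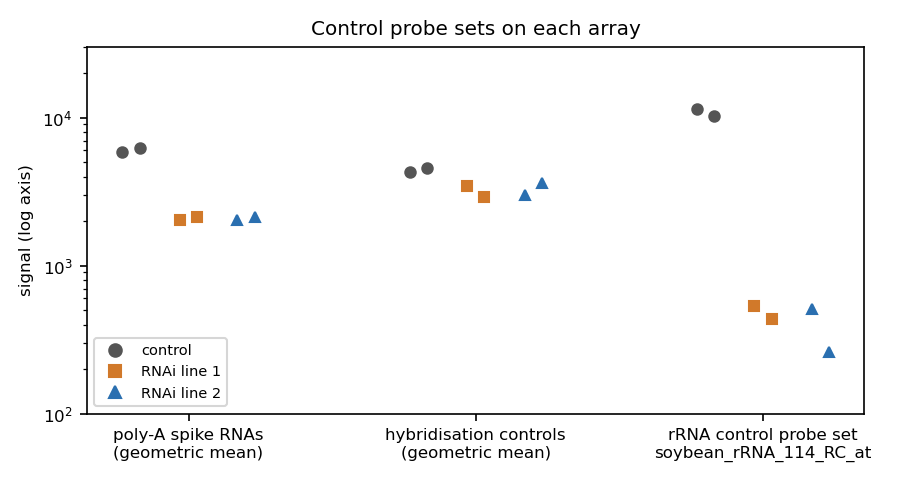
Signal of the control probe sets on each array (vertical axis, log scale; 1 point per array; spike and hybridisation controls as geometric means over their probe sets). The poly-A spike RNAs and the rRNA control probe set are lower on all 4 RNAi arrays, 2019 to 2139 and 260 to 535, than on the control arrays, and the hybridisation controls are lower by less.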

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

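Each test of an explanation in this part was chosen after the result was seen. The poly-A spike RNAs, which enter no comparison, stood 2.897 times higher in the control than in the RNAi samples, on both control arrays against all 4 RNAi arrays. Hybridisation, washing or scanning as the whole cause is argued against by the hybridisation controls, which are added after labelling: their RNAi to control ratio was 2.096 times that of the spikes. A different amount of spike RNA relative to sample RNA, or a different labelling of it, may account for the shift, since the 4 spike RNAs shared nearly 1 ratio (highest over lowest 1.22). More polyadenylated RNA in the RNAi cotyledons stays open as well and cannot be told apart from it, because a shift of all soybean signal relative to the spikes (1.5281 in line 1 and 1.5412 in line 2, log2) follows from either.

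The control probe set soybean_rRNA_114_RC_at stood at 10804 in the control and 435 in the RNAi samples, a 24.8-fold difference, and 6 of the 48 soybean rRNA probe sets were at least 2-fold higher on both control arrays than on every RNAi array. Among the 23350 probe sets of other organisms, 5 were at least 2-fold higher on every RNAi array than on both control arrays, such as PsAffx.psHB002xJ21f_s_at (291 against 1011). In the other direction 10 were higher on both control arrays, such as PsAffx.CL3Contig2_s_at (3641 against 734).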

How the results depend on the processing

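Scaling to the poly-A spikes, and no filter together with an estimated correlation, were chosen after seeing the data. Calls between the RNAi lines and the control (451) numbered 0 after quantile normalization, median centring, no filter, a pseudocount of 1 or robust moderation, 3323 with a filter at the 99th percentile of background, 3547 with a pseudocount of 64, 8517 with an intensity trend, 5987 with arrays as replicates and 10196 with duplicateCorrelation (consensus correlation -0.29, against -0.313 and -0.317 in data simulated with no sample effect). The smallest adjusted p in the settings with 0 calls ran from 0.0506 to 0.193 over these 5, and all 451 kept their direction there. These settings use the same arrays and all 451 were at least 2-fold apart, so a turn of direction was hardly possible. Leaving out 1 array gave 0 to 1884 calls. With no filter more probe sets were tested and fewer called: 1065 for line 1, 1132 for line 2 and 826 the same way in both. An intensity trend gave 6902, 7334 and 5571. With arrays scaled to the poly-A spikes calls numbered 26420 for the RNAi lines against the control, 26329 for line 1, 26371 for line 2 and 25913 the same way in both, nearly all higher. Leaving out 1 array, with a lone array assumed to vary like the other groups, gave 329 to 2518 for line 1, 527 to 2045 for line 2 and 304 to 957 in both. Line 2 against line 1 gave 0 calls in every setting run, with 1382 to 2235 at an unadjusted p below 0.05.

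The same replicate number did not mark related arrays: between groups, the differences of replicate 2 and replicate 1 correlated across probe sets at 0.02, -0.01 and 0.02. With the replicate number as a block, calls for the RNAi lines against the control numbered 4485 on the 6 arrays, against 5987 on the 6 arrays without it. They numbered 2201 for line 1, 2545 for line 2 and 1775 in both.

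Of 17 gene lists camera called 3, 0 with an estimated correlation, and 3 with any 1 array left out or with arrays scaled to the spikes. With no filter it called 4 of 18, beta-conglycinin among them, and 0 of 18 when the correlation was also estimated. On the 3 sample means an estimated correlation leaves camera 1 residual degree of freedom, on which a list could hardly pass, so these losses do not decide. On the 6 arrays, with 3 residual degrees of freedom, it called 0 of the 17 as well, with a smallest adjusted p of 0.437. Fry was run on the 6 single arrays, so its p-values measure technical spread, and it does not compare a list with other genes. It called 8 of the 17, including ER folding, heat shock, vacuolar, cell division and flavonoid lists that camera did not call. Of 1559 values of named probe sets over 18 alternatives, 944 kept direction and side of the threshold, 267 passed it anew, 313 lost it and 35 changed sign. After quantile normalization these were the GY4 probe sets, at 0.048 and 0.035. With arrays scaled to the spikes, an offset of 1.48 at the median probe set turned these upward: GY4 (1.323 and 1.341), GY5 (1.275), GY1 (0.545 and 0.698), GY2 (0.109), the shared beta-conglycinin probe set (0.6), CG-1 (0.442), PRP2 (0.02), SBPRP (0.1), VLXC (0.645), LOC547835 (1.05), NRP-A (0.777), HSF-08 (0.839), VPE2 (0.959), GDH1 (0.686), ASP1 (0.702) and FAD2-1A (0.224). It likewise turned FAD2-3 (0.242), LOC547684 (0.711), GBSSIa (0.735), NDHK (0.521), LOC547819 (0.837), TUBB2 (0.961), TUBB (1.005), RPL2 (0.934), RPL37 (1.22), NDR1b (0.406), LOC547822 (1.044), HIR1 (1.155), LOC547499 (0.583), BZIP124 (0.169) and BZIP59 (0.493). Except where the number tested, the samples or the test changed, the cause was not tested. Signal over background limits dim probe sets: 66 higher calls were below background on both control arrays and 21 lower calls on all 4 RNAi arrays, so their changes are bounds.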

Other observations

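Some families beyond the fixed lists, chosen after their values were seen, held called members. Of 9 ferritin probe sets 5 fell, those of SFERH-2 and H-1, while SFERH-3 (0.47 and 0.42) and SFERH-4 (0.59) were not called and lay on the other side, a split of 6 lower and 3 higher that held after quantile normalization and median centring and became 4 and 5 with arrays scaled to the poly-A spikes, an alternative also chosen after seeing the data. SFERH-2 had the brightest ferritin probe set, at 18994 in the control and 7664 and 7160 in the lines. Of 15 probe sets of the gibberellin-regulated GASA family 3 rose, those of GASA4 (2.08), GASA9 (1.38) and GASA14 (1.25), and GASA14 also had 1.15 (adjusted p = 0.0526) and 0.41 at its other probe sets. The family was split 9 higher to 6 lower, or 11 to 4 after quantile normalization and 15 to 0 with arrays scaled to the spikes, and its bright members GASA12, GASA22 and GASA27 had differences between -0.42 and -0.09. Of 7 SWEET probe sets only SWEET24 was called, and SWEET13 had 0.78 (adjusted p = 0.0646).

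Of the tests below, only that against random lists was chosen before its result was seen. Among the 10 storage protein probe sets with a control signal of at least 30000, those of GY4 and GY5 differed least from the control, though the shared beta-conglycinin probe set and 1 of GY1 were brighter there. Compression near the top of the measured range may contribute: over other genes the spread of changes at control signals of at least 30000 was 0.3139 times that at 1000 to 3000. That spread fell over the whole range of control signals, however, from 0.53 below 100 to 0.25 at 10000 to 30000. A smaller spread at the top therefore does not by itself show compression. The changes of the 10 storage protein probe sets spanned 2.5411 on the log2 scale, against 0.3165 for 3 median absolute deviations of the other genes there, so signals of that level were able to fall. GY4 (-0.21 and -0.19) and GY5 (-0.26) lay within 1 median absolute deviation (0.11) of the median of those other genes, -0.19, which does not set them apart from it. A smaller reduction of their transcripts, or none, and compression of unequal levels both stay open, and the labels do not give the target of the construct.

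Of the 39 LEA and dehydrin probe sets 20 were called higher in both lines. A rise of all signals of that level is argued against by 10000 random lists matched on mean signal: the list's median of 0.4081 lay above the upper bound of the middle 95% of them, 0.0725, and above the highest, 0.208. A hypothesis is that control and RNAi cotyledons of the same weight differed in stage of maturation, for which genes of early development would be lower in the lines. The medians of the lists that bear on it were -0.1805 for photosynthesis and 0.07 for cell division and histones, but the latter turned to -0.059 and -0.033 without control replicate 1 or 2, and to -0.001 and -0.018 without replicate 2 of line 1 or line 2, where both lists lie on the side the hypothesis needs. A median this near 0, over 9 higher and 7 lower probe sets, does not decide, so stage and the RNAi itself cannot be told apart with 1 control sample.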
